A study of Drosophila melanogaster with 11 samples.

How the data were processed

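RNA was measured in salivary glands and wing discs of 3rd instar Drosophila melanogaster larvae that were wild type (w1118) or homozygous for the dCap-D3 allele c07081. Per the labels, stocks were kept at 25 C, each salivary sample pooled 50 tissues and each wing disc sample pooled 150, and total RNA was extracted with TriZol and cleaned on RNeasy columns. The libraries were non-directional for salivary glands and directional for wing discs, and were read as 50 bp paired ends on a HiSeq2500. There were 3 salivary wild-type, 3 salivary mutant, 3 wing wild-type and 2 wing mutant libraries. By the labels the salivary libraries are numbered 22 to 27, wing wild-type replicates 1 to 3 are libraries 28, 29 and 59, and the wing mutants are libraries 30 and 31. The protocol speaks of 8 samples where 11 are listed and does not name them. Whether library 59 was made or sequenced apart from the rest is not given, so the wing wild-type spread, and with it the wing comparison, may include a difference between batches. The labels do not say whether samples of a group came from separate cultures, so every p-value measures only the spread between these samples.

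The deposited count table gives raw counts per gene for 11 libraries. The submitters' processing notes name Trim Galore 0.3.3, FastQC 0.11.3, BWA, TopHat2 2.0.8b, Picard 1.119, HTSeq 0.6.1 and the build BDGP6. Which aligner served which step, how shared reads were treated and whether strand was used in counting are not given in the sources used here. Reads shared between near-identical genes, and, in the non-directional salivary libraries, reads of overlapping genes on opposite strands, can therefore not be assigned with certainty. Overlaps on the opposite strand are named below for some genes only, and other named genes have them too. The table had 16034 entries, of which 11021 carried a symbol, and 15758 lay at the position of a gene in the BDGP6 annotation. Of the 5013 entries without a symbol, 4837 were named by position, and 176 stayed unnamed, with the entries without a symbol holding 0.0063% to 0.0278% of a library's counts. Septin gene symbols that a spreadsheet had turned into dates were left as they stood, and 31 entries had a damaged chromosome name. Gene positions are those of the deposited table.

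For each tissue the authors deposited a comparison table of 11021 genes. Per the file headers it holds a log2 fold change, a log2 mean CPM, a likelihood ratio statistic that is a score, a p-value and a false discovery rate. The tool behind it is not given in the sources used here, although the column names are those of edgeR's likelihood ratio test. The sign of Cap-D3 shows that the deposited log2 values are mutant over wild type. The deposited lists of gene identifiers follow from the same tables and were not used here.

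The libraries held 52483185 to 157639957 counts. A count of 0 in a library allows up to 3 counts, which is 0.0426 to 0.0572 CPM (counts scaled to a common library size) in salivary libraries and 0.019 to 0.0504 CPM in wing libraries. Intervals and floors cover counting error only. CPM values were scaled by the trimmed mean of M-values. Pairs of libraries of 1 group differed by a chi-square per degree of freedom of 22.3 to 1801, and no pair held identical values.

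Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3, because the library kind differs between tissues. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15. The test was the quasi-likelihood F-test with robust, legacy dispersions, and genes with a Benjamini-Hochberg adjusted p of at most 0.05 were called changed. Adjusted p-values below come from this test unless another is named, and ± after a log2 fold change is its standard error, taken as the log2 fold change divided by the square root of F. The biological coefficient of variation was 0.328 in salivary glands and 0.374 in wing discs. The tissue by genotype interaction was tested with the same tool on all 11 libraries. Gene lists, 35 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with at least 5 measured members, adjusted over the lists of a comparison. No camera call in either tissue or in the interaction held with an estimated correlation. The overlap of tissues was tested with Fisher's exact test.

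The tests, gene lists, groups, named-gene rule and most alternatives were fixed before the data were examined. The rule named Cap-D3 and w first. It then took genes that were called, changed at least 2-fold, had non-overlapping CPM ranges and reached a mean of 5 CPM in the higher group. Among them it named the 3 largest changes per direction, and the 6 largest per direction whose symbol is more than a CG or CR number. For each list it took up to 4 called members by adjusted p, or, without a call, up to 2 members of highest CPM. For the interaction it took 4 genes per direction by adjusted p, and for the overlap 4 genes per direction by the smaller of the 2 changes, plus those of opposite direction.

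The tests were tried on simulated data with known changes. For salivary glands 25.8% of 2-fold, 81.5% of 4-fold and 85.1% of 8-fold changes were recovered. Of 137 calls in this single simulated set 10 were false, or 7.30%, above the 5% aimed at. For wing discs 7.02%, 54.4% and 79.5% were recovered, with 4.72% of calls false, and for the interaction 1.64%, 39.4% and 59.3%, with 3.13% false. Alternatives were other size factors (RLE, upper quartile, total counts only), no filter or a mean of 5 CPM, no glue genes, DESeq2 1.42.0, limma-voom with sample quality weights, the newer quasi-likelihood form, 1 fit of all 11 libraries, a 2-fold minimum and each library left out in turn. The likelihood ratio test, fits without 2 wild-type libraries, camera on the interaction and camera with Cap-D3 left out of its lists were added after seeing the data. The planned test of neighbouring genes moved all calls along an arm together, which keeps nearly all neighbouring pairs, so calls placed at random within each arm were used instead.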

Results

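Counts per gene were compared between wild-type and dCap-D3 mutant larvae in 2 tissues. dCap-D3 is a subunit of condensin II, a complex that shapes chromosomes, and c07081 is a piggyBac insertion allele. The salivary gland is a secretory organ of large polytene cells, and the wing disc is a sheet of dividing diploid cells that forms the adult wing. Salivary wild-type replicates 1 to 3 held 52483185, 57349302 and 61644480 counts, and mutant replicates 1 to 3 held 54153356, 70369254 and 63398807. Wing wild-type replicates 1 to 3 held 61533957, 65095670 and 157639957, and wing mutant replicates 1 and 2 held 64839792 and 59495487. The 10 most abundant genes took 39.0% to 48.0% of counts in salivary libraries and 7.62% to 9.05% in wing libraries. Mitochondrial genes took 0.98% to 1.36% of counts in salivary wild type, 1.66% to 1.83% in salivary mutant, 0.559% to 1.81% in wing wild type and 2.69% to 2.83% in wing mutant.

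The first question was whether the mutation lowered its own gene. Cap-D3 (FBgn0051989, 2L, 5525905 to 5535958 on build BDGP6) fell in mutant salivary glands (log2 fold change -6.33 ± 0.22, adjusted p = 1.43e-04), from 4.799 ± 0.422 to 0.0578 ± 0.0077 CPM (SD, n = 3 and 3). In wing discs Cap-D3 stood at 18.6 ± 6.63 CPM in wild type (SD, n = 3) and 2.77 ± 0.223 CPM in the mutant (SD, n = 2). The log2 fold change of -2.75 ± 0.38 (adjusted p = 0.0916) did not pass the threshold, although the CPM ranges of the genotypes did not overlap. The wild-type counts in wing replicates 1 to 3 were 1072, 785 and 4398, against 189 and 151 in the mutant. Cap-D3 overlaps CG7277 and tomb on the opposite strand and CG31648 and CG31915 on its own strand. The white gene w, an eye pigment transporter that also serves as a marker in insertions of this type, rose in wing discs (log2 fold change 3.18 ± 0.26, adjusted p = 0.0259), from 1.48 ± 0.292 to 13.4 ± 0.337 CPM (SD, n = 3 and 2). In salivary glands w had a log2 fold change of -0.41 ± 0.27 (adjusted p = 0.354), and the difference between tissues passed its own test (3.45 ± 0.45, adjusted p = 0.0107). However, w overlaps kirre on the opposite strand, and the non-directional salivary libraries cannot set reads of the overlap apart. The wing call for w held without wild-type replicate 3 and ended without any other library, the adjusted p reaching 0.3998 without mutant replicate 2.

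**Figure D1:**
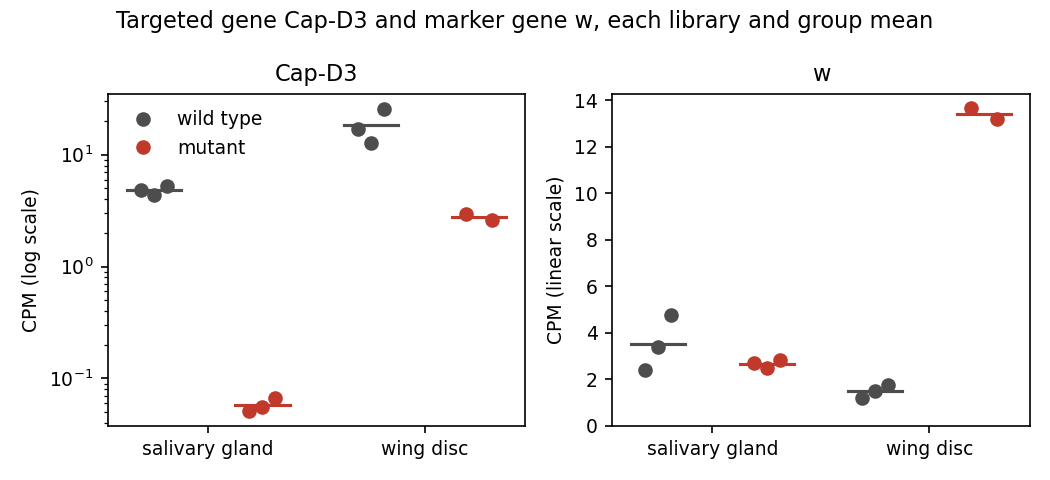
CPM (counts scaled to a common library size) of Cap-D3 (left, log axis) and w (right, linear axis from 0) in each library, with a line at each group mean. Cap-D3 lay near 0.0578 CPM in mutant salivary glands, where wild type had 4.799, and w averaged 13.4 CPM in mutant wing discs, where wild type had 1.48.

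The salivary comparison asked which genes changed in polytene cells that carry the dCap-D3 mutation. Heat shock genes rose together: 13 of 18 measured members rose and 0 fell (13 and 2 adjusted over the list alone), with a median log2 fold change of 1.83 (camera adjusted p = 2.31e-11, adjusted p = 0.448 with an estimated correlation). Hsp68 (FBgn0001230, 3R, 24055080 to 24057310), a stress-induced Hsp70-type chaperone, went from 3.903 ± 3.296 to 396 ± 251 CPM (SD, n = 3 and 3; log2 fold change 6.66 ± 0.88, adjusted p = 0.0092). The small heat shock gene Hsp26 rose from 34.02 ± 9.97 to 863 ± 347 CPM (log2 fold change 4.66 ± 0.41, adjusted p = 0.0026). The co-chaperone gene stv rose from 33.9 ± 4.54 to 242 ± 38.7 CPM (log2 fold change 2.83 ± 0.18, adjusted p = 8.94e-04). Hsp70Ab (6.60 ± 0.40, adjusted p = 7.38e-04) and Hsp70Bbb (4.98 ± 0.45, adjusted p = 0.0028) also rose, although reads can be shared between near-identical copies such as these. On the opposite strand Hsp68 overlaps CG6000 and Hsp70Ab overlaps CG3281. The 5 heat shock genes named here kept their calls when any 1 library was left out, and their highest adjusted p was 0.0419 without wild-type replicate 2.

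Genes for immune peptides moved both ways. In the list of antimicrobial peptides and immune effectors 9 of 25 measured members rose and 4 fell (12 and 6 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 0.0041, adjusted p = 0.448 with an estimated correlation). The list summed to 2080, 4815 and 1595 CPM in wild-type replicates 1 to 3. In mutant replicates 1 to 3 it summed to 4049, 2442 and 3338 CPM, so its summed level did not separate the genotypes. AttC (FBgn0041579, 2R, 13393705 to 13394667), an attacin, rose from 0.0357 ± 0.0179 to 14.7 ± 1.01 CPM (SD, n = 3 and 3; log2 fold change 8.60 ± 0.25, adjusted p = 5.42e-05). On the opposite strand AttC overlaps CG4744. The drosomycin-like gene Drsl1 rose by 2.79 ± 0.30 on the log2 scale (adjusted p = 0.0049). The immune-induced peptide genes IM14 (-7.41 ± 0.71, adjusted p = 0.0034) and IM4 (-6.91 ± 0.76, adjusted p = 0.0051) fell, as did AttD (-4.49 ± 0.80, adjusted p = 0.0225). These genes kept their calls without any 1 library except AttD, which reached an adjusted p of 0.0993 without mutant replicate 2. Among immune signalling genes 2 of 31 measured members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0303, adjusted p = 0.691 with an estimated correlation). The 2 that rose were the Toll pathway kinase pll (0.47 ± 0.09, adjusted p = 0.0294) and Fadd (0.48 ± 0.10, adjusted p = 0.0315). Both calls ended in every fit that left out 1 library, at adjusted p values up to 0.114 without mutant replicate 3 and 0.0993 without wild-type replicate 2.

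Among glue genes, which encode the secretion that fixes the pupa, 2 of 14 measured members rose and 3 fell (3 and 4 adjusted over the list alone). Pig1 (FBgn0003086, X, 3248600 to 3249289) rose from 11.3 ± 1.47 to 849.9 ± 87.99 CPM (SD, n = 3 and 3; log2 fold change 6.23 ± 0.18, adjusted p = 5.42e-05). The new glue gene ng2 rose from 38.8 ± 13.4 to 295 ± 147 CPM (log2 fold change 2.93 ± 0.45, adjusted p = 0.0151). Sgs7 (-0.77 ± 0.11, adjusted p = 0.0119) and Sgs8 (-0.58 ± 0.09, adjusted p = 0.0132) fell. Pig1 and ng2 lie within dnc on the opposite strand. The list's median log2 fold change was -0.04 and its mean 0.49, and camera found no shift (adjusted p = 0.876). The salivary prolyl hydroxylase gene PH4alphaSG2 fell from 214 ± 29.9 to 41.03 ± 8.93 CPM (log2 fold change -2.38 ± 0.21, adjusted p = 0.0026). It was the only called member among 26 secretory identity genes, whose median was 0.01 and mean -0.08 (camera adjusted p = 0.997). Pig1 and PH4alphaSG2 kept their calls without any 1 library, while ng2 reached an adjusted p of 0.0505 without wild-type replicate 2, Sgs7 of 0.0713 without mutant replicate 2 and Sgs8 of 0.091 without mutant replicate 3. PH4alphaSG2 overlaps PH4alphaMP on the opposite strand.

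Of detoxification genes, 10 of 52 measured members rose and 7 fell (17 and 10 adjusted over the list alone), and camera found no shift (adjusted p = 0.139). The cytochrome P450 genes Cyp4p2 (log2 fold change 7.04 ± 0.26, adjusted p = 1.75e-04) and Cyp6a17 (log2 fold change 6.87 ± 0.73, adjusted p = 0.0049) rose. The P450 gene Cyp4p1 (-3.06 ± 0.17, adjusted p = 6.24e-04) and the peroxiredoxin gene Prx2540-2 (-3.06 ± 0.17, adjusted p = 6.24e-04) fell. Prx2540-2 has a near-identical copy with which reads can be shared. Cyp4p1 and Cyp4p2 lie within hig on the opposite strand. Other large rises were those of CG13560 (FBgn0034899, 2R, 23747560 to 23748477, from 1.59 ± 0.681 to 1399 ± 709 CPM; log2 fold change 9.78 ± 0.66, adjusted p = 0.0011). The cytochrome c oxidase subunit gene mt:CoII rose from 0.687 ± 0.161 to 596 ± 30.2 CPM (log2 fold change 9.76 ± 0.26, adjusted p = 5.42e-05). Large rises also included CG32581 (9.58 ± 0.44, adjusted p = 3.98e-04) and Osi17 (6.69 ± 0.44, adjusted p = 8.94e-04). Each of these calls held without any 1 library. Large falls outside the lists above included CG3868 (-7.59 ± 0.58, adjusted p = 0.0016), the dopamine transporter gene DAT (-5.81 ± 0.59, adjusted p = 0.0042) and nol (-5.93 ± 0.79, adjusted p = 0.0096), the last reaching an adjusted p of 0.0618 without mutant replicate 2. CG7715 (-10.18 ± 2.39, adjusted p = 0.0486) and CG43896 (-9.49 ± 2.01, adjusted p = 0.0368) also fell, but their wild-type means were 26.6 ± 38.8 and 35.1 ± 51.97 CPM (SD, n = 3). With 1 library left out they reached adjusted p values of 0.1897 without mutant replicate 3 and 0.164 without mutant replicate 3.

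Markers of other tissues also differed. Of fat body markers, 4 of 18 measured members rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.691 with an estimated correlation). They included the storage protein gene Lsp1alpha, from 891 ± 235 to 7662 ± 2413 CPM (log2 fold change 3.10 ± 0.33, adjusted p = 0.0047), Obp99b (1.80 ± 0.26, adjusted p = 0.0126), Fbp2 (2.49 ± 0.37, adjusted p = 0.0132) and Desat1 (1.117 ± 0.20). Lsp1alpha alone kept its call without any 1 library, and the others reached 0.0541 without mutant replicate 3, 0.0662 without mutant replicate 3 and 0.0821 without wild-type replicate 2. The fat body gene Fbp1 stood at 39188 to 60850 CPM in all 6 salivary libraries, so transcripts of this kind were abundant in both genotypes. Of hemocyte markers 1 of 19 measured members rose and 5 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.709 with an estimated correlation). Hml (-1.65 ± 0.21, adjusted p = 0.0074), Pxn (-1.36 ± 0.25, adjusted p = 0.0256) and atilla (-1.18 ± 0.22, adjusted p = 0.0257) fell and NimC1 (1.75 ± 0.34, adjusted p = 0.0271) rose. Hml lost its call in 1 fit, at 0.0533 without mutant replicate 3, and the other hemocyte genes reached 0.114 without mutant replicate 3, 0.106 without mutant replicate 3 and 0.106 without wild-type replicate 2. Of muscle markers 0 of 26 measured members rose and 3 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.691 with an estimated correlation). The obscurin gene Unc-89 fell (log2 fold change -2.46 ± 0.19, adjusted p = 0.0017), as did the actin gene Act87E (-1.37 ± 0.30, adjusted p = 0.0401) and tn (-1.77 ± 0.42, adjusted p = 0.048). Unc-89 kept its call without any 1 library, while Act87E reached 0.136 without wild-type replicate 2 and tn reached 0.167 without mutant replicate 3. Of trachea markers 0 of 12 measured members rose and 2 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.691 with an estimated correlation). The 2 were pio (-0.99 ± 0.13, adjusted p = 0.0094, up to 0.0618 without mutant replicate 2) and btl (-1.57 ± 0.30, adjusted p = 0.0278, up to 0.0847 without wild-type replicate 3).

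Of cuticle genes, 0 of 24 measured members rose and 5 fell (1 and 12 adjusted over the list alone, camera adjusted p = 3.82e-04, adjusted p = 0.4702 with an estimated correlation). They included the larval cuticle genes Lcp1 (-5.86 ± 1.30, adjusted p = 0.042), Lcp2 (-5.39 ± 0.85, adjusted p = 0.0159) and Lcp4 (-5.44 ± 0.92, adjusted p = 0.019). None of these 3 held in all fits without 1 library (up to 0.179 without mutant replicate 3, 0.0865 without mutant replicate 3 and 0.0979 without mutant replicate 3). Digestive genes stood out in wild-type replicates 1 and 2: the gut list summed to 1535 and 13760 CPM there, to 352 CPM in wild-type replicate 3, and to 242 to 276 CPM in the mutant. Of the gut list, 0 of 12 measured members rose and 1 fell (0 and 9 adjusted over the list alone), with a median of -5.67 (camera adjusted p = 0.0237, adjusted p = 0.691 with an estimated correlation). The maltase gene Mal-A8 was the 1 that fell (log2 fold change -7.66 ± 1.17, adjusted p = 0.0145), and its adjusted p reached 0.0876 without mutant replicate 3. Of wing disc patterning genes 1 of 57 measured members rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 3.84e-05, adjusted p = 0.691 with an estimated correlation). Egfr rose (0.88 ± 0.15, adjusted p = 0.0207). The Hedgehog pathway factor ci (-0.96 ± 0.16, adjusted p = 0.0187), mirr (-1.54 ± 0.28, adjusted p = 0.0242) and the Notch ligand gene Dl (-1.28 ± 0.25, adjusted p = 0.0285) fell. None of the 4 held in all fits without 1 library, the highest adjusted p being 0.135 without mutant replicate 3 for Dl, 0.114 without mutant replicate 3 for mirr, 0.106 without mutant replicate 3 for ci and 0.0878 without wild-type replicate 2 for Egfr. Of other imaginal disc markers only eya fell (-1.87 ± 0.39, adjusted p = 0.0348, up to 0.125 without mutant replicate 2), and the list moved down (camera adjusted p = 1.22e-04, adjusted p = 0.703 with an estimated correlation).

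Few genes of chromosome biology passed the test. Of condensin subunits, 0 of 7 measured members rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.691 with an estimated correlation). With the mutated gene Cap-D3 left out, the other 6 had a median of -0.63 (camera adjusted p = 0.0473, and 0.763 with an estimated correlation). The called 2 were Cap-D3 itself and Cap-G of condensin I (-0.38 ± 0.09, adjusted p = 0.0458). Cap-G lost its call in every fit that left out 1 library (highest 0.1502 without wild-type replicate 2). Of DNA damage genes 1 of 31 measured members rose and 3 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0197, adjusted p = 0.703 with an estimated correlation). The double-strand break gene mre11 rose (log2 fold change 1.96 ± 0.11, adjusted p = 6.24e-04) and the photolyase gene phr fell (log2 fold change -1.15 ± 0.11, adjusted p = 0.0028), and both held without any 1 library. However, mre11 overlaps Osi21 on the opposite strand, and the non-directional salivary libraries cannot set reads of the overlap apart. The partner gene of mre11, rad50 (-0.88 ± 0.16, adjusted p = 0.022) and Parp (-0.51 ± 0.09, adjusted p = 0.0182) fell, but reached 0.1098 without mutant replicate 2 and 0.119 without mutant replicate 3. In DNA replication, Psf1 of the GINS complex rose (log2 fold change 2.41 ± 0.14, adjusted p = 6.24e-04) and held without any 1 library. In that list 2 of 36 measured members rose and 1 fell (2 and 1 adjusted over the list alone), with no camera shift (adjusted p = 0.552). Of cohesin genes 0 of 14 changed, of RB, E2F and DREAM genes 0 of 11, of ribosome biogenesis genes 0 of 28 and of Notch targets 0 of 17. Ribosome biogenesis genes (camera adjusted p = 0.0217, adjusted p = 0.804 with an estimated correlation) and Notch targets (camera adjusted p = 0.014, adjusted p = 0.788 with an estimated correlation) moved down as lists. The mitotic genes moved down too (camera adjusted p = 0.0134, adjusted p = 0.801 with an estimated correlation), and only Kmn1 among them was called and rose (1.59 ± 0.28, adjusted p = 0.0208, up to 0.0794 without wild-type replicate 2). Kmn1 overlaps CG11699 on the opposite strand. The other imaginal disc markers summed to 49.0, 59.1 and 30.0 CPM in wild-type replicates 1 to 3. In mutant replicates 1 to 3 they summed to 22.5, 13.2 and 5.15 CPM. Whether these lists fell with the content of such tissue was not tested.

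In the salivary glands 961 of 9006 tested genes were called, 514 higher and 447 lower, and 630 of them changed at least 2-fold. The count was 361 without mutant replicate 2, 310 without mutant replicate 3, 543 without wild-type replicate 1, 359 without wild-type replicate 2 and 578 without wild-type replicate 3. Wild-type replicates 1 and 2 carried the digestive transcripts. A fit without both leaves 1 wild-type library, so its count cannot show how many calls those transcripts gave. With upper-quartile size factors, which moved the median of all genes from -0.04 to -0.14 (log2), 916 genes were called and the majority turned, with 382 higher and 534 lower, while a mean of 5 CPM left 579. DESeq2 called 2254 (1115 higher and 1139 lower) and limma-voom with quality weights 1897 (875 and 1022). The likelihood ratio test called 1409 (653 and 756) and 1 fit of all 11 libraries 909 (444 and 465). Lower genes were also the majority without mutant replicate 1 (489 and 582) and without wild-type replicate 3 (233 and 345).

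**Figure D2:**
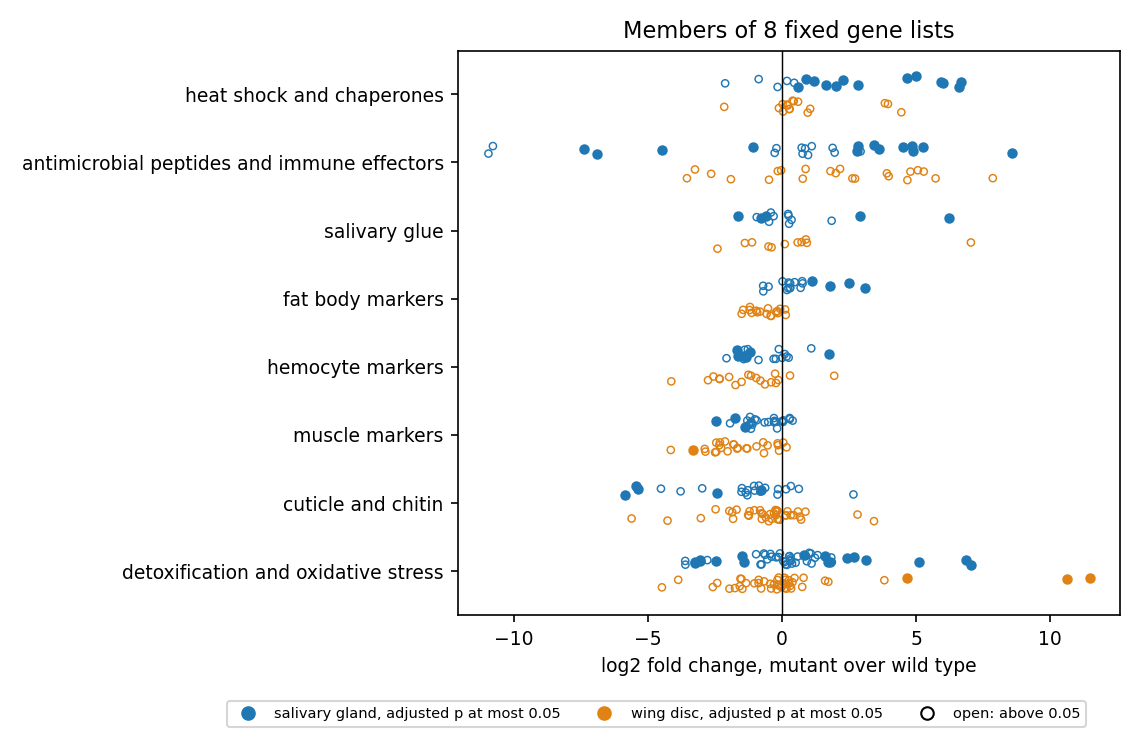
Log2 fold change (mutant over wild type) of each measured member of 8 gene lists fixed before the data were examined, in salivary glands (blue) and wing discs (orange). Filled points have an adjusted p of at most 0.05; 13 of 18 heat shock genes are filled and positive in salivary glands and none is filled in wing discs.

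The wing comparison asked the same of dividing diploid cells. Few genes were called, and several of those named had almost no counts in 1 genotype. CG32581 (FBgn0052581, X, 15796908 to 15799162) had 2 counts in the 3 wild-type libraries together, a ratio of 5120.4-fold, with a 95% counting interval of 1417 to 42294. Cyp6a17, a cytochrome P450, also had 2 wild-type counts (3678-fold, with a 95% counting interval of 1017 to 30384), and Ada1-1 had 1 (1920.0-fold, with a 95% counting interval of 344 to 75929.6). Cyp4p2 (FBgn0033395, 2R, 9237512 to 9239831) rose from 0.126 ± 0.049 to 189 ± 12.5 CPM (SD, n = 3 and 2; log2 fold change 10.65 ± 0.43, adjusted p = 0.0052). The mitochondrial gene mt:CoII rose from 3.09 ± 1.85 to 2206 ± 36.95 CPM (log2 fold change 9.49 ± 0.83, adjusted p = 0.0338). The ion channel gene ppk13 (8.44 ± 0.55, adjusted p = 0.0189) and swi2 (8.80 ± 0.81, adjusted p = 0.0338) rose too.

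CG3649 (FBgn0034785, 2R, 22845977 to 22847911) had no counts in mutant wing discs and was at least 1260-fold lower than its wild-type level of 61.9 ± 8.11 CPM (SD, n = 3), the floor being 3 counts in each mutant library. CG13032 had 1 count in the mutant, a ratio of 945-fold, with a 95% counting interval of 169 to 37325. The intraflagellar transport gene Oseg5 (-7.67 ± 0.52, adjusted p = 0.0189), the ABC transporter gene FBgn0010549 (2R, 9390165 to 9395281, -6.19 ± 0.42, adjusted p = 0.0189) and pinta (-4.72 ± 0.25, adjusted p = 0.0106) fell. So did the muscle myosin gene Mhc, from 7.06 ± 1.17 to 0.713 ± 0.0672 CPM (SD, n = 3 and 2; log2 fold change -3.30 ± 0.32, adjusted p = 0.0338). Ady43A (from 92.4 ± 9.03 to 23.1 ± 0.935 CPM) and CHKov2 (-1.95 ± 0.19, adjusted p = 0.037) fell as well. Of detoxification genes 3 of 45 measured members rose and 0 fell (4 and 0 adjusted over the list alone), the third being Cyp6a14 (4.65 ± 0.47, adjusted p = 0.0396), with a median of -0.12 and a mean of 0.17 (camera adjusted p = 0.467).

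Lists moved in wing discs mostly without called members. Of muscle markers 0 of 27 measured members rose and 1 fell (0 and 3 adjusted over the list alone), with a median of -1.79 (camera adjusted p = 1.61e-09, adjusted p = 0.642 with an estimated correlation). Hemocyte markers (0 higher and 0 lower of 19, 1 and 6 adjusted over the list alone, camera adjusted p = 4.49e-06, adjusted p = 0.642 with an estimated correlation) moved down. So did germline markers (0 higher and 0 lower of 23, 2 and 10 adjusted over the list alone, camera adjusted p = 8.72e-06, adjusted p = 0.6697 with an estimated correlation). The germline median was -3.94, or -3.30 with genes at 0 set to their bound. Fat body transcripts stood apart in wing wild-type replicate 2, where that list summed to 17882 CPM against 2445 to 5375 CPM in the others, and abd-A, a gene of abdominal segments, had 167 counts. The germline list summed to 44.6 CPM in that library and to 26.6 to 32.4 CPM in the others, and the sperm gene Mst87F had 116 counts there and 10 to 39 elsewhere. Hemocyte markers summed to 1199.9 CPM in wild-type replicate 3 and to 553 to 591 CPM in the others. Immune effector genes (median 2.09, 0 higher and 0 lower of 22, 4 and 3 adjusted over the list alone, camera adjusted p = 2.08e-04, adjusted p = 0.6697 with an estimated correlation) moved up. So did Notch targets (camera adjusted p = 2.22e-04, adjusted p = 0.6697 with an estimated correlation) and heat shock genes (camera adjusted p = 3.20e-04, adjusted p = 0.6697 with an estimated correlation), with no called member. The immune effector list summed to 56.6, 163 and 38.1 CPM in wild-type replicates 1 to 3. In mutant replicates 1 and 2 it summed to 134 and 50.4 CPM, so its summed level did not separate the genotypes. DNA replication genes moved down by a median of -0.22 (camera adjusted p = 0.009, adjusted p = 0.642 with an estimated correlation). PCNA stood at 423 ± 117 CPM in wild type (SD, n = 3) and 406 ± 7.97 CPM in the mutant (SD, n = 2). Gut markers also moved down (camera adjusted p = 0.0047, adjusted p = 0.642 with an estimated correlation). Of 58 wing disc patterning genes and 43 mitotic genes none was called, with medians of -0.04 and -0.01 and camera adjusted p values of 0.573 and 0.638 in the upward direction. The mitotic kinase gene polo stood at 394 ± 58.2 CPM in wild type (SD, n = 3) and 375 ± 2.48 CPM in the mutant (SD, n = 2).

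In wing discs 46 of 9689 tested genes were called, 30 higher and 16 lower, all changed at least 2-fold, and 924 had an unadjusted p under 0.05. The count was 0 without mutant replicate 1, mutant replicate 2 or wild-type replicate 1 (432, 395 and 805 genes at an unadjusted p under 0.05), 30 without wild-type replicate 2 and 45 without wild-type replicate 3 (library 59), so no named wing gene held in all fits. The loss of calls without a mutant replicate was partly set by the design, since 1 mutant library then remained and the spread came from wild type alone. In these 2 fits all 46 genes had the same direction as before. The absolute change in log2 fold change had a median of 0.08 and 0.07 and reached 2.76 and 1.06. Standard errors were larger by a median of 1.55 and 1.58 times. The genes had been selected with both mutants in the fit, and these were closely alike, so the kept direction was largely fixed by that selection. CG32581 had a log2 fold change of 12.03 ± 0.43 with all libraries, 12.03 ± 0.69 without mutant replicate 1 and 12.06 ± 0.69 without mutant replicate 2. Its wild-type counts were close to none, so these errors are narrower than its counting interval and understate the uncertainty. For CG13032, which had 1 mutant count, the values were -9.52 ± 0.76, -12.28 ± 1.15 and -8.70 ± 0.87 in the same order. The majority turned with DESeq2, which called 577 (228 higher and 349 lower), the likelihood ratio test, 469 (194 and 275), and limma-voom with quality weights, 1458 (709 and 749). The count was 140 with all 11 libraries in 1 fit and 1384 without wild-type replicates 2 and 3, where 1 wild-type library was left and the spread came from the 2 mutants, the most alike pair of all (chi-square per degree of freedom of 22.3).

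The interaction asked whether the effect of the mutation differed between tissues. It was called for 92 of 10850 genes, 34 with a higher and 58 with a lower effect in wing discs. Salivary libraries were non-directional and wing libraries directional, so library kind differed along with tissue. For genes that overlap others on the opposite strand, a difference may therefore include how reads were counted. CG5707 fell in salivary glands (log2 fold change -3.12 ± 0.53, adjusted p = 0.0188) and rose in wing discs (log2 fold change 5.86 ± 0.41, adjusted p = 0.0189), a difference of 8.82 ± 0.72, adjusted p = 0.0015. Its salivary call held in 3 of 6 fits that left out 1 library, and reached 0.104 without mutant replicate 3. The gene swi2 rose in wing discs and had a log2 fold change of -0.03 ± 0.32 in salivary glands, a difference of 8.63 ± 0.85, adjusted p = 0.0048. CG5039 fell in salivary glands (-5.15 ± 0.22, adjusted p = 3.11e-04) and stood at -1.26 ± 0.36 in wing discs, a difference of 3.78 ± 0.37, adjusted p = 0.0048. Oseg2, of intraflagellar transport, rose in wing discs (6.20 ± 0.44, adjusted p = 0.0189) and stood at -1.25 ± 0.46 in salivary glands, a difference of 7.26 ± 0.73, adjusted p = 0.0048. CR43461 rose in salivary glands (log2 fold change 4.44 ± 0.11, adjusted p = 5.42e-05) and stood at -0.19 ± 0.35 in wing discs, a difference of -4.75 ± 0.32, adjusted p = 6.17e-04. CG3649 fell in both tissues, with a fitted difference of -10.25 ± 0.62, adjusted p = 6.17e-04, a size that depends on the prior count since the wing mutant had no counts. Tsp42Ei, a tetraspanin gene (-3.20 ± 0.33, adjusted p = 0.0051), and Psf1 (-2.29 ± 0.25, adjusted p = 0.0071) had lower effects in wing discs, after rises of 2.38 ± 0.19, adjusted p = 0.002 and 2.41 ± 0.14, adjusted p = 6.24e-04 in salivary glands. Tsp42Ei reached 0.0531 without wing mutant replicate 2 and Psf1 0.0621 without wing mutant replicate 1, and the other 6 of these 8 genes held without any 1 library. The Cap-D3 difference was 3.45 ± 0.47, adjusted p = 0.0121. The count was 262 (181 higher and 81 lower) without salivary mutant replicate 1, 38 and 56 without salivary mutant replicates 2 and 3, 50, 60 and 179 without salivary wild-type replicates 1 to 3 (the last 2 with 33 and 112 higher), 12 and 7 without wing mutant replicates 1 and 2 (9 and 5 of them higher, 1 wing mutant library being left), and 58 without wing wild-type replicate 1. DESeq2 called 584 (310 higher and 274 lower), limma-voom with quality weights 1506, the likelihood ratio test 528 and a mean of 5 CPM left 25.

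The overlap asked whether the same genes changed in both tissues. Of 8300 genes tested in both, 23 were called in both, 22 of them in the same direction (12 higher and 10 lower), where 1.27 higher and 0.62 lower were expected by chance. CG32581, mt:CoII, Ada1-1 and Cyp4p2 were higher in both. In salivary glands Ada1-1 had 1 wild-type count, a ratio of 226-fold, with a 95% counting interval of 40.3 to 8976. CG13032, CG18278, the ABC transporter gene FBgn0010549 and CG3649 were lower in both. CG18278 had no counts in mutant salivary glands, at least 32.7-fold lower with a floor of 3 counts in each library, and a log2 fold change of -6.51 ± 0.69 in wing discs. CG5707, the 1 opposite gene, was lower in salivary glands and higher in wing discs. It dropped out of the overlap without salivary mutant replicate 2, salivary mutant replicate 3 or salivary wild-type replicate 2. Fisher's exact test (two-sided) gave an odds ratio of 14.6 and p = 1.46e-14, which treats genes as independent, and they are not. Across the genes tested in both, log2 fold changes had a Pearson r of 0.421 and a Spearman rho of 0.183. The same-direction count was 0 without wing mutant replicate 1, wing mutant replicate 2 or wing wild-type replicate 1, and 14 and 13 without salivary mutant replicates 2 and 3. DESeq2 gave 176 and the likelihood ratio test 134.

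**Figure D3:**
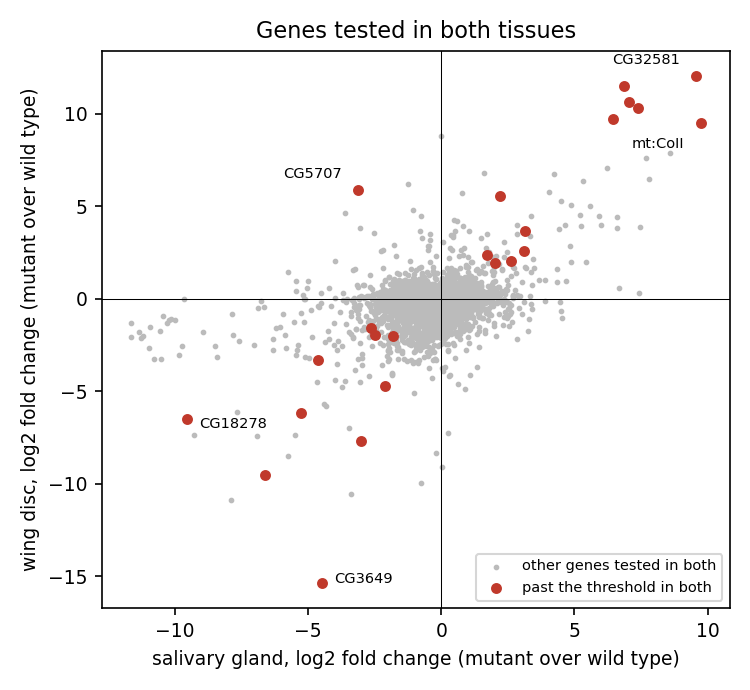
Log2 fold change (mutant over wild type) in salivary glands (x axis) and wing discs (y axis) for the 8300 genes tested in both. Red points passed the threshold in both tissues; 22 of the 23 lie in the quadrants of equal sign, and CG5707 does not.

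The authors' deposited tables were set beside these fits. Both rest on the same libraries, so shared direction and a high r were largely fixed in advance and are no separate support. In salivary glands the authors called 1822 genes, 484 higher and 1297 lower by at least 2-fold, and 1338 of the called genes were tested here. Of these 638 were called here and 1337 had the same direction, and log2 fold changes had an r of 0.989 across genes. A further 315 genes called here were not called by the authors. At the same 2-fold minimum the salivary calls here were 309 higher and 321 lower. In wing discs the authors called 1439, 404 higher and 820 lower by at least 2-fold, and 1172 were tested here. All 46 genes called here were called by the authors, 1172 of 1172 had the same direction, and r was 0.934 across genes. The authors' log2 fold change for Cap-D3 was -6.37 in salivary glands and -2.60 in wing discs. The false discovery rates deposited with the authors' likelihood ratio statistic were 5.7e-30 and 2.0e-23, so Cap-D3 passed in both tissues there.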

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

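The sample splits and the interaction test of single genes were planned, and camera on the interaction, with and without Cap-D3, and the tests of mitochondrial, both-tissue and digestive genes were chosen only after the results were seen.

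Every result here was marked because the mutant effect differed between the tissues by the test of the interaction, and each value is the wing minus the salivary log2 fold change. The interaction was called for 92 genes. Library kind differed along with tissue, so differences for genes with overlaps on the opposite strand may include it. Cap-D3 differed by 3.45 and w by 3.45. Of 19 heat shock and chaperone genes 4 passed, all with the lower effect in wing discs, among them Hsp68 by -6.20, Hsp26 by -3.84 and stv by -2.78. Hsp70Ab (-2.83 ± 1.30, adjusted p = 0.406) and Hsp70Bbb (-0.91 ± 6.98, adjusted p = 0.9999) did not pass. Of the P450 genes, Cyp4p2 differed by 3.43 and Cyp4p1 by 6.77. Of genes of DNA replication and repair, Psf1 differed by -2.29 and mre11, which overlaps Osi21 on the opposite strand, by -1.51. The ecdysone-induced gene ImpE3 differed by 2.37 and CG3868 by 5.19. Genes with a higher effect in wing discs also included swi2 at 8.63, CG5707 at 8.82, CG5039 at 3.78 and Oseg2 at 7.26. Genes with a lower effect included CG3649 at -10.25, CR43461 at -4.75, Oseg5 at -4.76, pinta at -2.77, CHKov2 at -1.94 and Tsp42Ei at -3.20.

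Lists that differed between tissues with the preset correlation, none of which held with an estimated one, are given as medians. Higher in wing discs were condensin subunits (0.33, but 0.18 and camera adjusted p = 0.267 without Cap-D3), mitotic genes (0.62), immune effectors (0.80), wing disc patterning genes (0.63), Notch targets (1.20), cuticle genes (0.98), trachea markers (0.76), gut markers (2.42, where salivary wild-type replicates 1 and 2 held 1535 and 13760 CPM of that list and replicate 3 held 352) and other imaginal disc markers (1.0). Lower in wing discs were heat shock genes (-1.56), glycolysis genes (-0.50), fat body markers (-1.32), muscle markers (-1.13) and germline markers (-4.70). Germline genes numbered 23 in this test but 5 in the salivary fit, gut genes 31 and 12, and cuticle genes 41 and 24. The added members had too few salivary counts to be tested there, so these 3 medians rest in part on salivary values near the floor. Wing wild-type replicate 2 held 17882 CPM of the fat body list, against 2445 to 5375 CPM in the other wing libraries, and 44.6 CPM of the germline list, against 26.6 to 32.4.

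For the gene counts, the real grouping of salivary libraries gave 961 genes and the highest of the other splits gave 0, 1 of 10 splits reaching the real count. In wing discs the real grouping gave 46 and the highest other 0, again 1 of 10. At an unadjusted p under 0.05 the real wing grouping held 924 genes. Wild-type replicates 1 and 3 set against the other wing libraries held 863. In salivary glands the real grouping held 2650 and the highest other split 864. With 10 splits the share cannot fall under 0.05.

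Mitochondrial mRNA counts were higher in the mutant: 9 of 11 measured mitochondrial mRNAs rose in salivary glands and 2 of 12 in wing discs. More mitochondrial RNA of every kind is argued against in salivary glands. There the mitochondrial ribosomal RNA mt:lrRNA had a log2 fold change of -0.04 ± 0.11 and the mRNA median was 2.29. In wing discs mt:lrRNA had 0.49 ± 0.56 and the mRNA median was 2.20. That wing margin was thin and left out the error of the median, so the wing values do not decide. The gene mt:ND6 had 0 counts in the 6 wild-type libraries and 64 in salivary and 125 in wing mutants. The log2 fold changes of 11 mitochondrial mRNAs had a Spearman rho of 0.93 between tissues (permutation p = 1.70e-04, two-sided), so mitochondrial sequence that differs between the stocks may alter which reads align. A gene-specific effect of the mutation would give the same rho and stays open, untested.

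Genes changed the same way in both tissues numbered 22, of which 2 were mitochondrial. Of the 20 nuclear genes 10 lie on other chromosomes and 10 on chromosome 2, which held 38.2% of tested genes, and 0 lie within 2 Mb of Cap-D3. Variants on chromosome 2 carried along with the Cap-D3 mutation stay open, since 20 genes are too few to decide. Of the 22, 9 were at or under 0.2 CPM in all libraries of 1 genotype in both tissues. Differences between the stocks that are unrelated to Cap-D3 could give such genes, and, with 1 stock per genotype, they cannot be told apart from an effect of dCap-D3.

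The gut list, which holds digestive enzyme genes, had a median log2 fold change of -5.67 in mutant salivary glands (camera adjusted p = 0.0237, and 0.691 with an estimated correlation). Of its 12 measured genes 1 was called lower, and 9 were when adjusted over the list alone. Jon65Aiv, which was not called (adjusted p = 0.0627), stood at 495, 6132 and 1.78 CPM in wild-type replicates 1 to 3 and at 0.602, 1.52 and 0.714 CPM in the mutant, and alphaTry, too rare in the other libraries to be tested, at 252, 500.3 and 0.174 CPM in wild type. Gut tissue carried into wild-type replicates 1 and 2 is a candidate source, because the median log2 ratio of wild-type replicate 3 to the mutant mean was 0.97 over the list, against 4.15 and 4.84 for replicates 1 and 2. That 0.97 was close to the bound of 1 set for it. An effect of dCap-D3 stays open for part of the list. In 7 of 12 list genes all wild-type libraries lay above all mutant libraries. Carried-over gut tissue would by itself put replicates 1 and 2 on top, so this count cannot separate the explanations.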

How the results depend on the processing

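The likelihood ratio test, the fits without 2 wild-type libraries, camera on the interaction, camera without Cap-D3 in its lists and the random order of calls within arms were chosen after seeing the data. No paired analysis was possible because the labels share no replicate numbers between the groups. Salivary glands gave 961 genes, and 2254 with DESeq2, 1897 with limma-voom and quality weights (which change the tool and the weights at once), 579 with a mean of 5 CPM and 630 at 2-fold. Leaving out 1 library gave 310 (without mutant replicate 3) to 1071 (without mutant replicate 1), and leaving out wild-type replicates 1 and 2 gave 92, where 1 wild-type library is assumed to vary like the mutants. Of 94 salivary genes taken by the named-gene rule, 28 stayed on their side of the threshold in that fit, 66 no longer passed it and 0 called genes reversed. Wing discs gave 46, and 577 with DESeq2, 1458 with weighted limma-voom, 469 with the likelihood ratio test, 140 with all 11 libraries in 1 fit, 77 with the newer quasi-likelihood form, 26 with a mean of 5 CPM and 1384 without wild-type replicates 2 and 3, where 1 wild-type library was left and the spread came from 2 closely alike mutants. Leaving out 1 library gave 0 (without either mutant replicate or wild-type replicate 1) to 45. The fits with 0 held 432 (without mutant replicate 1), 395 (without mutant replicate 2) and 805 (without wild-type replicate 1) genes at an unadjusted p under 0.05. In that 1384-gene fit Ppn reversed to 0.44 ± 0.06 from -0.23 ± 0.62, the only reversal of a gene taken by the named-gene rule and called in either fit, and neither fit settles its direction. The interaction gave 92, and 584 with DESeq2, 1506 with weighted limma-voom, 528 with the likelihood ratio test and 25 with a mean of 5 CPM, and 7 (without wing mutant replicate 2) to 262 (without salivary mutant replicate 1). The same-direction overlap gave 22, and 176 with DESeq2, 134 with the likelihood ratio test and 0 (without either wing mutant replicate or wing wild-type replicate 1) to 30. Lists past camera numbered 16 in salivary glands, 0 with an estimated correlation, 16 without Cap-D3 in its lists and 14 to 17 without 1 library. In wing discs they numbered 8, 0 with an estimated correlation, 8 without Cap-D3 in its lists, 19 without wild-type replicate 2, 16 without wild-type replicate 3 and 7 at the lowest. fry, which tests a list against no change and not against other genes, passed 7 salivary lists, 2 of which did not pass camera, and 0 wing lists. Fewer genes entered the 5 CPM and 2-fold counts by construction; for the rest the cause was not tested. Other size factors, no filter and no glue genes, where run, kept each total within 1.5 times. By direction the wing calls were 25 higher and 8 lower with upper-quartile factors, and the salivary calls 442 higher and 293 lower with no filter. Of 85 called salivary genes taken by that rule, 33 held in all fits without 1 library, as did 0 of 19 in wing discs, where 1 mutant library was left in 2 of the fits, and 6 of 8 in the interaction. The wing tests recovered 54.4% of simulated 4-fold changes, so a wing gene that was not called is not shown to be unchanged.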

Other observations

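The tests of neighbouring genes and of genes near Cap-D3 in this part were chosen or changed only after the positions of the called genes were seen.

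In 5 further lists 1 or 2 members were called in salivary glands, while camera found no shift of the JNK and wound (adjusted p = 0.552), glycolysis (0.148), Hippo (0.165), neuron (0.218) or germline (0.915) list. The lists not described elsewhere also had no camera shift. Their calls were ecdysone response (0 higher and 2 lower of 30, 0 and 4 adjusted over the list alone), programmed cell death (2 higher and 0 lower of 19, 2 and 0 adjusted over the list alone), autophagy and lysosome (1 higher and 0 lower of 28, 0 and 0 adjusted over the list alone) and chromatin silencing (1 higher and 1 lower of 47, 1 and 1 adjusted over the list alone). Further calls were in juvenile and growth hormones (1 higher and 0 lower of 20, 0 and 0 adjusted over the list alone), sex composition (0 higher and 1 lower of 8, 0 and 1 adjusted over the list alone) and condensin II interactors (0 higher and 1 lower of 9, 0 and 2 adjusted over the list alone), the last being Cap-D3. Of salivary gland markers 3 of 10 were called lower (5 adjusted over the list alone, camera adjusted p = 0.0874). In the JNK and wound list 2 of 23 measured members rose and 0 fell (4 and 2 adjusted over the list alone). The 2 were the TNF gene egr (log2 fold change 1.77 ± 0.30, adjusted p = 0.0195), which reached 0.0822 without mutant replicate 3, and Ets21C (log2 fold change 2.34 ± 0.55, adjusted p = 0.0471), which lost its call in every fit that left out 1 library. The glycolytic genes Gapdh2 (log2 fold change 0.59 ± 0.12, adjusted p = 0.0318) and Pgi (log2 fold change 0.94 ± 0.20, adjusted p = 0.0389) rose, and reached 0.122 without wild-type replicate 2 and 0.133 without wild-type replicate 2. The growth regulator ex of the Hippo pathway fell (log2 fold change -1.02 ± 0.13, adjusted p = 0.0084) and held without any 1 library, and so did unc-13, a gene of synaptic vesicle release (log2 fold change -1.98 ± 0.21, adjusted p = 0.0047). Both ex and unc-13 overlap genes on the opposite strand. The sperm gene Mst87F rose from 0.779 ± 0.222 to 3.25 ± 0.826 CPM (log2 fold change 2.06 ± 0.33, adjusted p = 0.0159), and reached 0.0761 without mutant replicate 2.

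Called genes lay next to each other more often than calls placed at random within each chromosome arm. In salivary glands 101 neighbouring, non-overlapping pairs changed in the same direction, where random order gave a median of 42 and at most 61 (permutation p = 0.001, one-sided, the smallest that 1000 orders can give). In wing discs there were 3 such pairs, where random order gave at most 2 (permutation p = 0.001, one-sided), so the wing result rests on very few pairs. Among the called wing genes, CR44383 (X, 15796477 to 15796897) ends just before CG32581 (X, 15796908 to 15799162), and both were higher in the mutant. Whether genes this close are separate transcripts was not tested. Neighbouring genes may therefore change together, although shared tissue content, co-regulated gene clusters and stock differences would do the same and were not separated. The planned shifts of all calls along an arm kept 114 to 117 of 117 salivary pairs, overlapping ones included, so they could not test this.

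Variants linked to the Cap-D3 mutation were weighed as a source of the salivary changes. Of 321 tested genes within 2 Mb of Cap-D3, 36 changed, or 11.2% (95% Clopper-Pearson interval 7.98% to 15.2%), where the rest of arm 2L had 11.3% and the other arms 10.4% (1000 shifts, one-sided permutation p = 0.522). The interval lies under 20.8%, 2 times the share of other arms, so called genes were not concentrated near Cap-D3 to that degree. With 321 tested genes the window could not hold most of the changes whatever the outcome. Effects of linked variants on genes outside the window were not tested, so the share of the change they account for stays open. In wing discs 0 of 333 genes in that window were called.

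Wing wild-type replicate 3, library 59, had 157639957 counts, and whether it was made or sequenced apart from the others is not given. The wing wild-type libraries all differed from each other by the span of the gene. The log2 ratio of replicate 3 had a Spearman rho with span of 0.682 against replicate 1 and 0.708 against replicate 2, and that of replicate 2 against replicate 1 had a rho of -0.553 (9689 genes, which are not independent replicates). The trend was therefore not confined to replicate 3, and its cause was not tested.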
